A study of Homo sapiens with 12 samples.

How the data were processed

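Gene expression was measured in U-2 OS cells, an established human osteosarcoma line, that stably expressed either the wild-type glucocorticoid receptor (WT-GR) or a receptor with serine 404 changed to alanine (S404A-GR). Per the labels, both lines were kept for 48 h in medium with 10% charcoal-stripped serum, which removes steroid hormones. They were then treated with 100 nM dexamethasone, a synthetic glucocorticoid, for 6 h or left as the 0 h control. The series design calls the control vehicle, whereas the sample descriptions call it not treated, and it is called vehicle here. If it was taken at 0 h, as the labels read, 6 h of time and handling could not be separated from dexamethasone. Changes given below for dexamethasone include any such effect. Each of the 4 groups held 3 arrays. The labels call the arrays triplicates and do not say that they came from separate cultures, so every p-value measures the spread between these arrays, which may be technical. Each receptor form was carried by a line of its own, so receptor and line could not be separated.

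Per the series design, cytoplasmic RNA was harvested, whereas the labels give the molecule as total RNA. A 500 ng portion was labelled with Cy3, and 1.65 µg of labelled cRNA was hybridized for 17 h to an Agilent human whole-genome oligonucleotide array with 1 colour. The deposited scanner files hold the processed intensity of each spot on a linear scale, which the authors obtained with Agilent Feature Extraction 9.5 at its 1-colour defaults, per the submitters' processing notes and the series design. The headers name the hg17 genome build. The series' value table holds log2 values in 12 columns that the authors deposited for the same arrays. Across the probes well above background on its own array, each column correlated with the log2 processed intensity at r = 0.9996 or above. The medians of the columns were 8.12 to 8.24. The scale was therefore read from the values, whereas the scaling between arrays that the authors applied to that table remains unknown. The table was used only as an alternative.

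Each array carried 43376 non-control spots of 41000 probes. The share of probes well above background was 69.1% to 77.9% per array, the signal at the 75th percentile was 2245 to 3509 intensity units, and at most 1 probe per array was saturated. With 3 arrays per group, the number of arrays limits the precision. For the main analysis, log2 of the processed signal minus the 75th percentile of each array was taken, and spots that the scanner software called non-uniform, or outliers among replicate spots, were treated as missing. Spots of the same probe were averaged. A probe was tested if it was well above background on all 3 arrays of at least 1 group and measured on at least 2 arrays of every group, which left 31317 probes. Probes were named through a table of current RefSeq gene names. This matched 23434 probes by accession, 2317 by symbol, 1043 by an older symbol and 35 by a further accession, while 14171 kept the name in the files. A gene was represented by its tested probe with the highest mean signal, which gave 23343 genes or unnamed features, 14971 of them with a current symbol. Named genes with another tested probe of a different call are pointed out.

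limma 3.58.1 in R 4.3.3 was used to fit all 12 arrays with 1 mean per group, so that the groups shared an estimate of spread with 8 residual degrees of freedom per gene before moderation. The two-sided moderated tests were adjusted by the Benjamini-Hochberg procedure over the genes, with a threshold of 0.05. The 5 comparisons fixed in advance were the dexamethasone effect in each line, the difference between these effects (the interaction, S404A-GR minus WT-GR), and the difference between the lines without and with dexamethasone. The last was planned as a secondary comparison. A gene whose probes were not well above background on any array of a group has only a bound there, as have the shown probes of CRISPLD2 and G6PC1 in S404A-GR cells. Its fold is given as "at least", from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the probe's own signal.

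The rule for named genes was written before the data were examined. It takes, for each of the first 4 comparisons, the 10 largest rises and 10 largest falls among genes with a current symbol, measured above background in all groups compared and with no overlap between arrays. For 3 arrays against 3, chance gives such a separation in 10% of splits. It adds up to 3 bounds each way, the 4 members with the largest change of each gene list described, and the receptor gene NR3C1. The members of 19 gene lists were also fixed before the data were examined; 2 members had no probe. Which lists are described was decided after the list tests had been seen, as those called by the test plus, for both dexamethasone effects, the lists of classical glucocorticoid-induced genes, glucocorticoid-repressed inflammatory genes, metabolic genes and epithelial markers. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation and limma's fry as alternatives, and adjusted over the 19 lists of a comparison.

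The arrays lay on 3 slides of 4 arrays each. Slide 1 held the 3 WT-GR vehicle arrays and 1 WT-GR dexamethasone array, slide 2 held the other 2 WT-GR dexamethasone arrays with 2 S404A-GR vehicle arrays, and slide 3 held the rest. Scan dates followed the slides. The dexamethasone effects were computed within slides 1 and 3 as well, and slide was fitted as a block in all comparisons. The other alternatives were normexp background correction with an offset of 50, which shrinks the changes of dim genes by construction, including those given as bounds, quantile and median scaling, the value table, 2 other filters on dim probes, 2 other ways of using a gene's probes, a fit of only the arrays compared, an intensity trend with a robust prior, array quality weights, a replicate block, each array left out in turn, an adjusted p under 0.01, and minimum changes of 1.5-fold and 2-fold. Ranges of adjusted p over the alternatives leave out the other thresholds and, for lists, the other list tests.

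The fit was checked on simulated data with the real means and spreads of the 23343 genes, in which 100 genes were changed by a log2 size of 1 and 100 by 2. For those sizes, it recovered 85% and 97% in the WT-GR dexamethasone comparison, 87% and 95% in the S404A-GR one, 72% and 91% in the interaction, 76% and 94% between the lines without dexamethasone, and 84% and 97% between the lines with it. In that order, 5 of 187, 16 of 198, 2 of 165, 12 of 182 and 7 of 188 calls were false, a share above 5% for the S404A-GR comparison and for the lines without dexamethasone. The list test, simulated for the WT-GR comparison over the same genes, called 50 of 50 lists shifted by a log2 of 0.5 and 1 of 900 unchanged lists. In that simulation genes varied independently, list members were drawn at random and no gene outside the shifted list changed. It therefore does not show how often lists of correlated genes are falsely called in the real data. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.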

Results

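Transcripts were measured on 12 arrays of U-2 OS osteosarcoma cells, 3 arrays for each combination of line (WT-GR or S404A-GR) and treatment. The glucocorticoid receptor is a hormone-activated transcription factor, and the series title concerns its phosphorylation by the kinase GSK-3 beta. The comparisons address whether cells whose receptor lacks the serine replaced in S404A-GR respond differently to dexamethasone. Values are log2 differences ± SE from limma with n = 3 arrays per group, unless a fold is given, and positions are those of the probes on hg17. The first principal component, with 49.2% of the variance, separated the dexamethasone arrays from the vehicle arrays, and the second, with 34.5%, separated the lines. The median SD between the arrays of a group was 0.0864 for WT-GR vehicle, 0.141 for WT-GR dexamethasone, 0.0998 for S404A-GR vehicle and 0.111 for S404A-GR dexamethasone (log2).

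**Figure D1:**
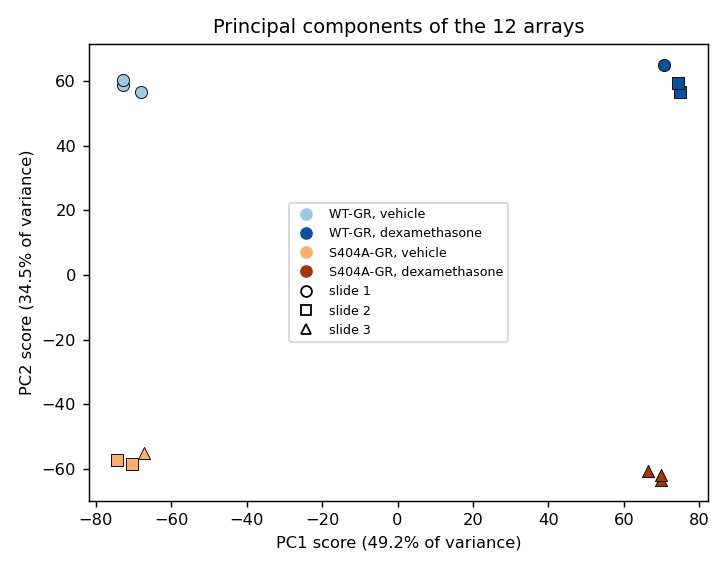
Scores of the 12 arrays on the first and second principal components of the log2 signals, with the share of variance on each axis; each point is 1 array, its colour gives line and treatment and its shape the slide. The first component (49.2%) separates the treatments and the second (34.5%) the lines, and arrays of 1 group on different slides lie together.

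In WT-GR cells, dexamethasone raised FAM90A1 (chromosome 12, 8265403 to 8265462) 916-fold (9.84 ± 0.10, adjusted p = 1.95e-12). HBM, which encodes a globin chain, rose 777-fold (9.60 ± 0.12) and the Notch ligand gene DLL1 167-fold (7.39 ± 0.09). The endothelin receptor gene EDNRA rose 92.5-fold (6.53 ± 0.40), the histidine-degrading enzyme gene FTCD 75.8-fold and ARC, a neuronal activity-regulated gene, 70.9-fold. PHACTR3, LGSN, FRG2 and the thyroglobulin gene TG rose 63.5-, 62.5-, 59.0- and 56.4-fold. KDF1, the gastric proton pump gene ATP4A and the retinal arrestin gene SAG were not well above background without dexamethasone and rose at least 222-, 186- and 163-fold. With normexp correction, whose offset shrinks the changes of dim genes, these 3 rose by 6.22, 6.16 and 5.65 on the log2 scale, less than these bounds. FAM90A1, FRG2 and the globin genes have relatives of similar sequence that their probes may also detect.

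The secreted metalloprotease gene ADAMTS6 had the deepest measured fall among the named genes of WT-GR cells, 54.9-fold (-5.78 ± 0.11, adjusted p = 5.1e-11). The receptor phosphatase gene PTPRR fell 29.5-fold (-4.88 ± 0.09), the dynamin gene DNM3 by 4.83 ± 0.14 on the log2 scale, and AMIGO2 27.3-fold (-4.77 ± 0.09). INHBE, which encodes a subunit of the activin family, fell 21.3-fold and the sialyltransferase gene ST6GALNAC5 15.97-fold. The log2 change was -3.94 for SERTAD4, -3.87 for ADAMTS1, -3.77 for the growth factor gene TGFB2 and -3.52 for RUNX1T1. KCTD4, KCNJ15 and CXCL8, which encodes a neutrophil-attracting chemokine, were not well above background after dexamethasone and fell at least 17.8-, 16.2- and 11.6-fold. Normexp correction gave -2.74, -2.26 and -2.11 for these and -2.00 for RUNX1T1.

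Of 33 classical glucocorticoid-induced genes, 25 rose, 4 fell and 4 were not called in WT-GR cells. CRISPLD2 rose 29.0-fold (4.86 ± 0.20), the G-protein regulator gene RGS2 26.9-fold (4.75 ± 0.08), the transcription factor gene KLF15 24.6-fold (4.62 ± 0.08) and PDK4, an inhibitor of pyruvate dehydrogenase, 23.6-fold (4.56 ± 0.11). In this comparison, 1 of 3 CRISPLD2 probes and 1 of 2 KLF15 probes had another call, and with the mean of a gene's probes these genes rose by 3.09 and 2.69. The list had a median of 1.20 and was called with camera (adjusted p = 2.14e-07), but not with an estimated correlation (adjusted p = 0.0559).

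Of 24 inflammatory genes known as glucocorticoid-repressed, 11 fell, 5 rose and 8 were not called in WT-GR cells. Those that fell included CXCL8, the chemokine gene CCL2 (-2.73 ± 0.09) and the cytokine gene CSF2, which was below background with dexamethasone (-2.71 ± 0.20, at least 1.53-fold; -0.49 with normexp correction). NOS2, the inducible nitric oxide synthase gene, rose 15.2-fold (3.92 ± 0.07). The list was not called (median -0.17, adjusted p = 0.114), and its median ranged from -0.44 to 0.07 over the alternatives.

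Of 23 immediate early genes, which respond rapidly to growth signals, 13 fell, 6 rose and 4 were not called in WT-GR cells. CCN1, a matrix-associated growth regulator gene, changed by -3.30 ± 0.08 and IER3 by -2.41 ± 0.08, whereas ZFP36, whose product promotes decay of cytokine mRNAs, rose (2.40 ± 0.09). The nuclear receptor gene NR4A3 fell by 2.57 ± 0.81 (adjusted p = 0.0210). Its call was lost in 4 of 19 alternatives, including slide as a block and the fit without WT-GR dexamethasone array 1 (adjusted p = 0.0513; range 8.32e-06 to 0.109), and without WT-GR vehicle array 2 the value was -1.30. The list was called (median -0.50, adjusted p = 0.0468), but not with an estimated correlation (adjusted p = 0.321). With slide as a block the median was -1.04 and the call was lost (adjusted p = 0.0983), as it was in 9 of 14 alternatives (range 0.0132 to 0.159). Among these were the fits without WT-GR vehicle array 1 (adjusted p = 0.0797), WT-GR dexamethasone array 2 (0.0540) and array 3 (0.0672).

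Of 14 heat shock genes, 7 fell, 1 rose and 6 were not called in WT-GR cells. The chaperone genes HSPA1A (-2.97 ± 0.06), DNAJB1 (-1.30 ± 0.06) and HSPH1 (-0.98 ± 0.08) fell, and HSPA6 rose (2.00 ± 0.09). Camera called this list (median -0.25, adjusted p = 0.0440), but not with an estimated correlation (adjusted p = 0.321). The call was also lost with slide as a block (median -0.35, adjusted p = 0.0665) and without WT-GR dexamethasone array 2 (adjusted p = 0.0540). Over 14 alternatives adjusted p ranged from 0.0112 to 0.0700. In S404A-GR cells 9 heat shock genes fell and 3 rose, and camera did not call the list (median -0.29, adjusted p = 0.196). The response difference between the lines was not called for this list either (camera, adjusted p = 0.128).

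In WT-GR cells, 12145 of 23343 genes changed, 6517 up and 5628 down (limma, adjusted p under 0.05). At least 2-fold changes comprised 2454 rises and 1199 falls, and at least 8-fold changes 500 rises and 60 falls. Adjusted over the list alone, 25 classical genes rose and 4 fell, 6 inflammatory genes rose and 11 fell, 7 immediate early genes rose and 13 fell, and 1 heat shock gene rose and 8 fell. With slide as a block 11194 genes were called, and within slide 1 10409. The slide holds 1 dexamethasone array, with the lowest quality weight of the 12 (0.262), so that the spread there came from its 3 vehicle arrays alone. All 4 arrays are also part of the full estimate, so this is no independent test. The median within slide 1 was 1.42 for the classical and -0.35 for the inflammatory list. Which direction prevailed depended on scaling. Quantile and median scaling shifted the median change of all genes from 0.06 to -0.02 and -0.07, and 6025 of 12716 and 4918 of 12237 called genes then rose.

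In S404A-GR cells, dexamethasone raised FAM90A1 2007-fold (10.97 ± 0.10, adjusted p = 6.54e-13), HBM 464-fold (8.86 ± 0.12) and the embryonic globin gene HBZ by 6.72 ± 0.20 on the log2 scale. CARD14, a signalling scaffold gene, rose 161-fold (7.33 ± 0.18), but by 0.90 with the filter on all 12 arrays, under which another probe represents it. DLL1 rose 97.2-fold (6.60 ± 0.09) and TAMALIN 73.8-fold (6.21 ± 0.09). PDK4 rose by 6.84 ± 0.11, the carbonic anhydrase gene CA2 by 5.94 ± 0.07, FLRT3 by 5.86 ± 0.08 and the potassium channel gene KCNA4 by 5.74 ± 0.11. SPINK13, ATP4A and ACTL8 were not well above background without dexamethasone and rose at least 211-, 192- and 189-fold, but with normexp correction by 5.62, 5.63 and 5.46 on the log2 scale.

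PTPRR had the deepest measured fall among the named genes of S404A-GR cells (-4.36 ± 0.09, adjusted p = 1.03e-10). The growth factor gene FGF5 fell 17.2-fold (-4.10 ± 0.22), NAV3 16.2-fold (-4.02 ± 0.15), ADAMTS1 13.3-fold and CXCL8 11.7-fold (-3.55 ± 0.20). CNIH3 fell 11.7-fold, with 1 of 2 probes of another call and -1.84 with the mean of both, and ADAMTS6 11.4-fold. The log2 change was -3.37 for RAB7B, -3.32 for DNM3 and -3.28 for F2RL2, a thrombin receptor gene. GPR65, PDCD1LG2 and the bradykinin receptor gene BDKRB1 were not well above background after dexamethasone and fell at least 15.6-, 4.96- and 4.95-fold. Normexp correction gave -1.90, -0.65 and -0.69 for these and -2.12 for CXCL8.

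Of the 33 classical glucocorticoid-induced genes, 25 rose, 3 fell and 5 were not called in S404A-GR cells. After PDK4, RGS2 rose 44.6-fold (5.48 ± 0.08) and KLF15 39.3-fold (5.30 ± 0.08), with 1 of 2 KLF15 probes of another call and 3.17 with the mean of both. The CRISPLD2 probe was not well above background without dexamethasone and rose at least 32.7-fold, but by 3.12 on the log2 scale with normexp correction. The list had a median of 1.75 and was called (adjusted p = 1.12e-07), but not with an estimated correlation (adjusted p = 0.0501).

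Of the 24 inflammatory genes, 12 fell, 7 rose and 5 were not called in S404A-GR cells. CXCL8, CSF2 (-3.15 ± 0.20) and the cytokine gene LIF (-3.05 ± 0.07) fell. The chemokine gene CXCL1 was well above background only with dexamethasone in this line and rose at least 3.60-fold (3.80 ± 0.25). With normexp correction CXCL1 rose by 1.18 and CSF2 changed by -1.31. The list was not called (median -0.67, adjusted p = 0.196; range over 14 alternatives 0.135 to 0.349).

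In S404A-GR cells, 15220 genes changed, 8320 up and 6900 down. At least 2-fold changes comprised 2566 rises and 1516 falls, and at least 8-fold changes 356 rises and 36 falls. Adjusted over the list alone, 25 classical genes rose and 3 fell, and 7 inflammatory genes rose and 12 fell. With slide as a block 13386 genes were called, and within slide 3 11489. The spread within slide 3 came from its 3 dexamethasone arrays alone, since it holds 1 vehicle array, and all 4 arrays are also part of the full estimate, so this is no independent test. The median within slide 3 was 1.67 for the classical and -0.70 for the inflammatory list. Which direction prevailed depended on scaling in this line too, with 7263 of 14943 called genes rising under quantile scaling, 7173 of 14751 under median scaling and 9132 of 14906 with normexp correction.

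FAM90A1, HBM, DLL1 and ATP4A were among the largest rises, and PTPRR, DNM3, ADAMTS1 and ADAMTS6 among the largest falls, named in both lines. The lines shared 9048 calls in the same direction, 4894 rises and 4154 falls, against 2322.8 and 1663.6 for independent calls, and 625 genes were called in opposite directions. Of changes of at least 2-fold, 1637 rises and 682 falls were shared and 29 genes went in opposite directions. Across genes, which are not independent replicates, the log2 changes of the lines had a Pearson's r of 0.787 and a Spearman's rho of 0.718, and these comparisons share no arrays.

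**Figure D2:**
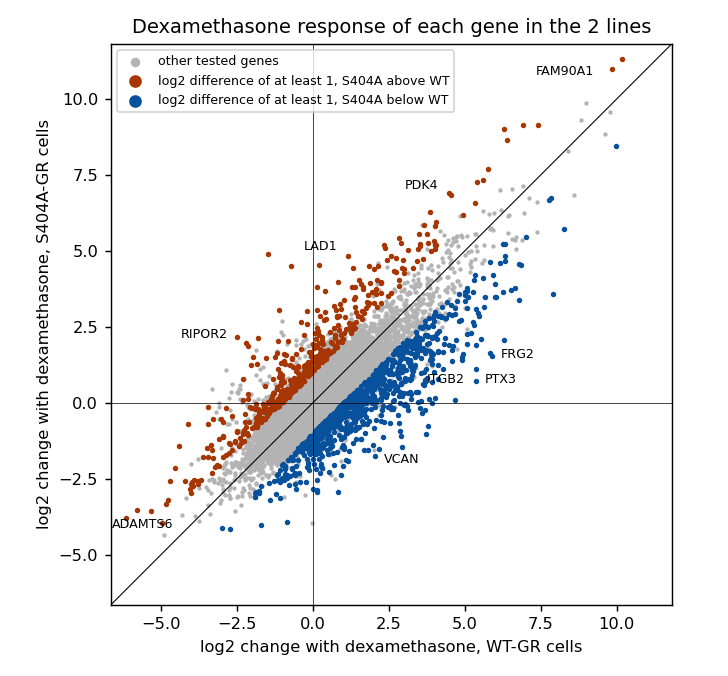
Log2 change with dexamethasone of each of the 23343 genes in WT-GR cells (horizontal) and S404A-GR cells (vertical), 3 arrays per group; the diagonal marks equal changes. Brown and blue points are the 507 and 926 genes with an interaction call and a log2 difference of at least 1, S404A-GR above or below WT-GR, and across all genes r was 0.787.

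The receptor gene NR3C1 (brighter probe on chromosome 5, 142641130 to 142641189) fell by 1.28 ± 0.08 with dexamethasone in WT-GR cells (2.43-fold, adjusted p = 2.2e-07) and changed by -0.87 ± 0.08 in S404A-GR cells (1.83-fold lower, adjusted p = 4.14e-06). The difference of 0.41 ± 0.11 was called (adjusted p = 0.0162), but 1 of 2 probes had another call. It was not called with slide as a block (0.22) or with the mean of both probes (0.23), and adjusted p ranged from 0.00334 to 0.226 over 24 alternatives. Without dexamethasone NR3C1 lay lower in the S404A-GR line (-0.21 ± 0.08, adjusted p = 0.0383). That call was lost in 9 of 19 alternatives (range 0.00949 to 0.876), among them slide as a block (-0.03) and the fits without WT-GR vehicle arrays 1 (-0.16) or 3 (-0.21) or S404A-GR vehicle arrays 1 (-0.19), 2 (-0.22) or 3 (-0.24). Whether the probes also detect the introduced receptor is not known, so these values check neither the labels nor the level of the transgene.

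RIPOR2 (chromosome 6, 24912721 to 24912780) fell with dexamethasone in WT-GR cells (-2.19) and rose in S404A-GR cells (1.96), a difference of 4.16 ± 0.15 (adjusted p = 1.42e-07). TXNIP, the thioredoxin-interacting protein gene (-0.95 and 1.60), TEX14 (-1.54 and 1.46) and CMKLR2 (-1.23 and 1.52) were also reversed. LAD1, a basement membrane protein gene, rose by 1.14 in WT-GR and 4.84 in S404A-GR cells, the potassium channel gene KCNH2 by 2.34 and 5.18, the bile acid binding protein gene FABP6 by 1.51 and 4.03, and HSPA6 by 2.00 and 4.39. INHBE (difference 3.00 ± 0.23) and the cytokine receptor gene IL21R (2.74 ± 0.12) fell less in S404A-GR cells. IL21R was already lower in the S404A-GR line without dexamethasone (log2 difference -6.07 to -4.83 over 19 alternatives). That difference was larger in size than its change with dexamethasone in WT-GR cells (-3.44).

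FRG2 (chromosome 4, 191321137 to 191321196) rose by 5.88 in WT-GR and 1.53 in S404A-GR cells, a difference of -4.35 ± 0.09 (adjusted p = 5.37e-09). The secreted pentraxin gene PTX3 rose by 5.36 and 1.11, the cytokine receptor gene IL3RA by 5.38 and 1.91, the leukocyte integrin gene ITGB2 by 4.57 and 1.37 and the chloride channel gene ANO1 by 4.27 and 1.10. The matrix proteoglycan gene VCAN rose in WT-GR cells (2.04) and fell in S404A-GR cells (-1.75). LBH (2.31 and -1.12; 1 of 2 probes had another call), ARHGAP25 (1.82 and -1.56), the T-cell receptor locus TRA (0.92 and -2.39) and EVA1A (1.00 and -2.08) were reversed in the same sense. The difference was -1.91 for LBH with the mean of its probes, and -2.01 for ANO1 and -1.63 for TRA with normexp correction. With dexamethasone VCAN reached like levels in the lines (log2 minus the 75th percentile, -3.99 to -3.73 in WT-GR and -3.92 to -3.77 in S404A-GR). The same held for ITGB2 (-0.07 to 0.14 and -0.01 to 0.14), so both lay apart mainly without dexamethasone. PTX3 and KCNH2 also lay further apart without dexamethasone than with it. PTX3 had -3.896 to -3.703 in WT-GR and 0.773 to 0.871 in S404A-GR cells without it. With it PTX3 had 1.497 to 1.636 and 1.852 to 2.067. KCNH2 had -3.129 to -2.876 and -5.819 to -5.204 without it, and -0.865 to -0.528 and -0.397 to -0.295 with it. TXNIP was the reverse, alike without dexamethasone (1.78 to 2.16 and 1.795 to 2.03) and apart with it. RIPOR2, LAD1 and FRG2 lay apart both without and with dexamethasone.

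**Figure D3:**
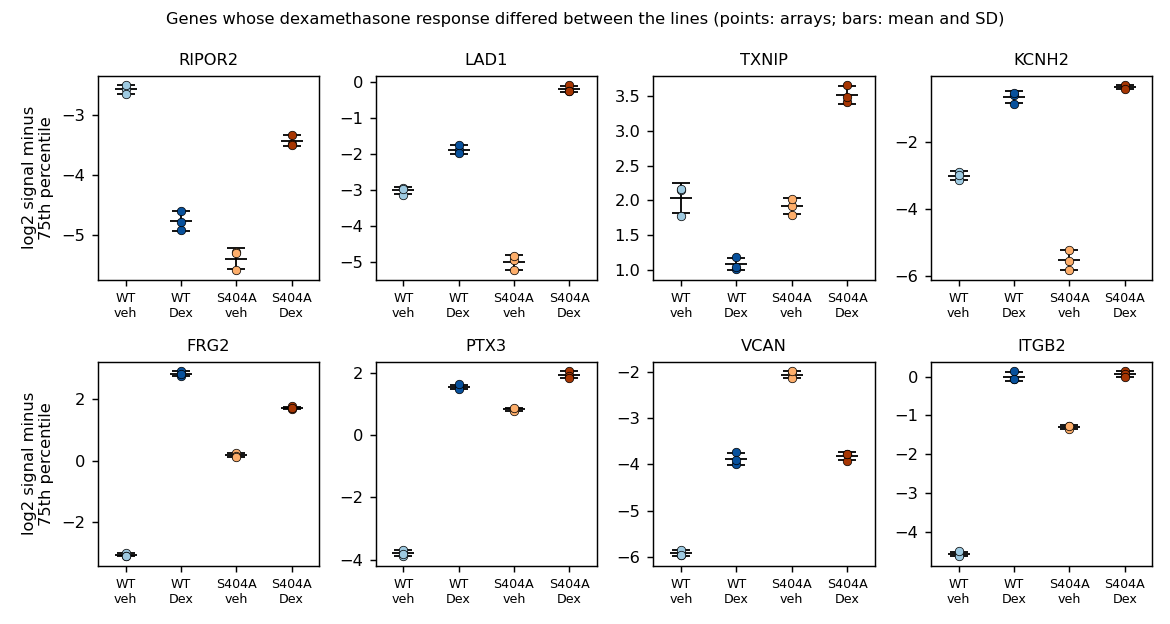
Log2 signal minus the array's 75th percentile for 8 genes whose dexamethasone response differed between the lines; points are the 3 arrays of a group and bars its mean and SD. RIPOR2 and TXNIP fell with dexamethasone in WT-GR and rose in S404A-GR cells, VCAN did the reverse, and FRG2, PTX3 and ITGB2, which were lower in WT-GR than in S404A-GR cells without dexamethasone, rose more in WT-GR cells.

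Of 23 immediate early genes, 11 had a higher log2 change in S404A-GR than in WT-GR cells and 0 a lower one, while KLF4 was not called (1.06 ± 0.83). Among the 11 were CCN1 (difference 1.75 ± 0.11) and the AP-1 genes JUNB (1.13 ± 0.09) and JUN (1.10 ± 0.30). These 3 fell in WT-GR cells (-3.30, -1.825 and -1.12) and changed less in S404A-GR cells (-1.56, -0.695 and -0.02). With slide as a block JUN had 1.78, and KLF4 ranged from 0.44 to 1.81 over the alternatives. The list was called (median 0.36, adjusted p = 1.26e-04), but not with an estimated correlation (adjusted p = 0.0909). JUNB was not called with the mean of its probes (1.97, adjusted p = 0.0961; range over 24 alternatives 9.96e-07 to 0.0961).

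Of 33 classical glucocorticoid-induced genes, 13 had a higher and 6 a lower log2 change in S404A-GR than in WT-GR cells, and 14 had no called difference. LAD1 (3.69 ± 0.15), PDK4 (2.28 ± 0.16), the cell cycle inhibitor gene CDKN1C (1.93 ± 0.13) and DDIT4, an inhibitor of mTORC1 signalling (1.92 ± 0.07), were higher. Camera called this list (median 0.38, adjusted p = 0.0148), but not with an estimated correlation (adjusted p = 0.228). It was not called with normexp correction either (median 0.26, adjusted p = 0.0538; range over 20 alternatives 0.00374 to 0.0538).

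Of 15 circadian clock genes, 7 had a higher and 1 a lower log2 change in S404A-GR than in WT-GR cells. PER1 (1.44 ± 0.10) and NFIL3 (1.04 ± 0.11) rose more in S404A-GR cells. NR1D2 (1.11 ± 0.14) fell in WT-GR cells (-1.115) and hardly changed in S404A-GR cells (-0.006). CLOCK, whose arrays varied, was not called (1.25 ± 1.5). Without WT-GR vehicle arrays 1, 2 or 3 the CLOCK value was 2.01, -0.40 or 2.14, and with slide as a block 0.68. The list was called (median 0.72, adjusted p = 0.0168), but not with an estimated correlation (adjusted p = 0.118) or with slide as a block (median 0.63, adjusted p = 0.0655; range over 20 alternatives 0.00390 to 0.0655).

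Of 25 p53 target genes, 7 had a higher and 2 a lower log2 change in S404A-GR than in WT-GR cells. The growth arrest gene GADD45A (1.38 ± 0.10) and PLK3 (0.69 ± 0.09) fell less in S404A-GR cells (-0.50 and -0.92) than in WT-GR cells (-1.88 and -1.61). SESN2 (0.83 ± 0.10) and the death receptor gene FAS (0.78 ± 0.12) fell in WT-GR cells and rose in S404A-GR cells. Camera called this list (median 0.23, adjusted p = 0.0393), but not with an estimated correlation (adjusted p = 0.135). The call was lost in 6 of 20 alternatives (range 0.0110 to 0.161), among them slide as a block (median 0.19) and the fits without WT-GR vehicle array 1 (adjusted p = 0.0529) or WT-GR dexamethasone array 2 (0.0522).

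A different response was called for 7411 genes (limma interaction). The log2 change was higher in S404A-GR cells for 3422 and lower for 3989 of them, but under median scaling it was higher for 3722 of 7001. Of the 1433 with at least a 2-fold difference, 540 rose more in WT-GR and 254 in S404A-GR cells, 173 fell more in WT-GR and 228 in S404A-GR cells, 234 went in opposite directions and 4 were called in neither line. Adjusted over the list alone, 12 immediate early genes were higher and 0 lower, against 15 and 6 classical, 7 and 2 clock, and 7 and 2 p53 target genes. No slide holds all 4 groups, and with slide as a block 7230 genes were called, 5090 of them among the 7411, with a median of 0.35 for the immediate early and 0.47 for the classical list. Across genes, the response difference had a Pearson's r of -0.331 with the difference between the lines without dexamethasone. Shared vehicle arrays alone make this negative, but the covariance of -0.175 was larger in size than the -0.040 simulated for them.

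Without dexamethasone, the S404A-GR line had 192-fold more PLEK2 (7.59 ± 0.11, adjusted p = 2.3e-11) and 98.4-fold more of the melanosome transport gene MLPH (6.62 ± 0.08) than the WT-GR line. The growth factor gene IGF2 was 52.6-fold higher, DTX3 52.1-fold, the smooth muscle actin gene ACTG2 51.8-fold, the protocadherin gene PCDH7 46.2-fold and ZNF542P 41.9-fold. ESM1 was 32.6-fold, TNFAIP2 30.9-fold and the microfibril gene MFAP5 27.9-fold higher. The hedgehog-binding protein gene HHIP, the phosphatase gene PTPN7 and the homeobox gene GSC were not well above background in the WT-GR line and were at least 109-, 30.1- and 25-fold higher, but PTPN7 by 3.19 and GSC by 3.5 on the log2 scale with normexp correction.

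BST2, the interferon-induced tetherin gene, was lower in the S404A-GR line by a log2 difference of -6.93 ± 0.11 (adjusted p = 4.97e-11). IL21R was 59.4-fold lower, MAP1LC3C 41.6-fold and MXRA8 26.7-fold. The log2 difference was -4.99 for the galectin gene LGALS9, -4.73 for STK31, -4.55 for FAM9B, -4.48 for the cytokine gene IL24, -4.29 for the interleukin receptor gene IL13RA2 and -4.24 for TMC5. The cartilage protein gene CILP and the gluconeogenesis gene FBP1 were not well above background in the S404A-GR line and were at least 35.7- and 19.9-fold lower. PASD1, at least 15.5-fold lower, varied between arrays (-5.34 ± 1.5, adjusted p = 0.0121) and lost its call in 3 of 18 alternatives, including slide as a block (range 7.86e-05 to 0.247). Without WT-GR vehicle array 2 its log2 difference was -3.0, smaller than that bound. Normexp correction gave -2.96 for FAM9B, -2.49 for TMC5, -3.11 for CILP, -2.35 for FBP1 and -2.61 for PASD1.

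Of 26 interferon-stimulated genes, 18 were lower and 4 higher in the S404A-GR line without dexamethasone. Next to BST2, the antiviral genes IFI35 (-2.55 ± 0.10) and IFIT2 (-2.45 ± 0.11) were lower, whereas IFI44L, not well above background in the WT-GR line, was at least 3.44-fold higher (1.04 with normexp correction). The list was called (median -1.01, adjusted p = 4.92e-05), but not with an estimated correlation (adjusted p = 0.0689).

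Of 10 metallothioneins, which bind metals, 8 were lower and 0 higher, with MT1M at -3.27 ± 0.12, MT1E at -1.74 ± 0.12, MT1A at -1.11 ± 0.09 and MT1H at -1.08 ± 0.08. Camera called this list (median -1.04, adjusted p = 4.99e-05), but not with an estimated correlation (adjusted p = 0.307), and its genes are so similar that probes may detect relatives. Of 14 heat shock genes, 8 were lower and 1 higher, with HSPA6 at -1.64 ± 0.09, the co-chaperone gene BAG3 at -1.15 ± 0.06, HSPA1A at -0.88 ± 0.06 and HSPB1 at -0.83 ± 0.06. That list was called (median -0.30, adjusted p = 0.0168), but not with an estimated correlation (adjusted p = 0.146).

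Of 24 inflammatory genes, 16 were higher and 2 lower in the S404A-GR line without dexamethasone. The collagenase gene MMP1 was at least 18.4-fold higher, the stromelysin gene MMP3 26.6-fold (4.73 ± 0.24), and the interleukin genes IL1A and IL1B at least 3.98- and 2.23-fold. With normexp correction the differences were 2.78 for MMP1, 1.15 for IL1A and 0.83 for IL1B. The list was called (median 0.93, adjusted p = 4.92e-05), but not with an estimated correlation (adjusted p = 0.0884). Of 31 bone and extracellular matrix genes, 22 were higher and 6 lower. CCN2 (2.80 ± 0.09), the osteoprotegerin gene TNFRSF11B (2.70 ± 0.10) and the alkaline phosphatase gene ALPL (2.40 ± 0.17; 1 of 3 probes had another call; 1.36 with the mean of its probes and 1.57 with normexp correction) were higher, and the collagen gene COL3A1 was lower (-2.81 ± 0.15). The matrix list was called (median 0.83, adjusted p = 1.01e-04), but not with an estimated correlation (adjusted p = 0.146).

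Of 23 immediate early genes, 13 were higher and 4 lower, with ZFP36 (1.45 ± 0.09), CCN1 (1.24 ± 0.08) and EGR1 (1.17 ± 0.07) higher. KLF4 was well above background on 2 of 3 WT-GR and 0 of 3 S404A-GR vehicle arrays, so its fitted difference (-1.59 ± 0.58, adjusted p = 0.0418) measures no size. It ranged from -3.28 with slide as a block to -0.45 with normexp correction, and the call was lost in 8 of 18 alternatives (range 0.0259 to 0.152). Among these were the fits without WT-GR vehicle array 1 (-0.96) or S404A-GR vehicle arrays 1 (-1.27), 2 (-1.75) or 3 (-1.73). Camera called this list (median 0.30, adjusted p = 0.0174), but not with an estimated correlation (adjusted p = 0.146). Of 25 p53 target genes, 10 were higher and 3 lower, with TP53I3 (1.02 ± 0.06), GADD45A (0.98 ± 0.07) and PHLDA3 (0.95 ± 0.11) higher and GDF15 lower (-1.60 ± 0.12). The p53 list was called (median 0.30, adjusted p = 0.0347), but not with an estimated correlation (adjusted p = 0.146).

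**Figure D4:**
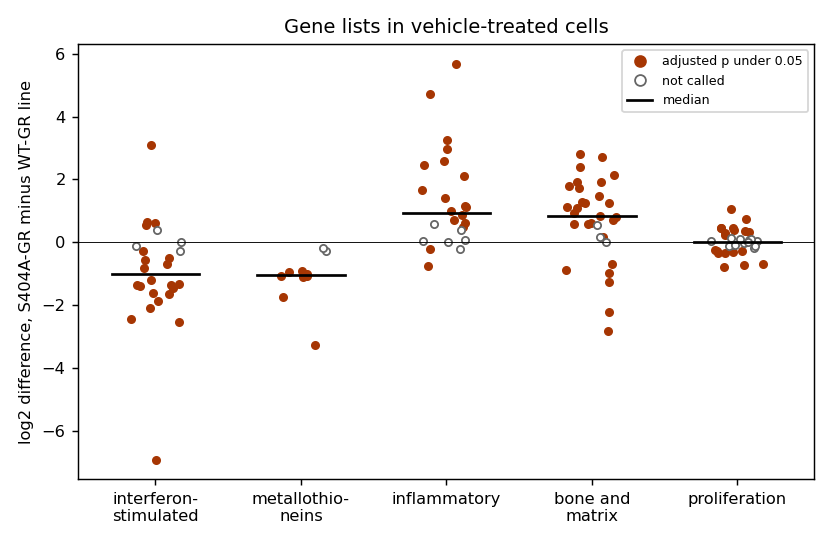
Log2 difference of the S404A-GR minus the WT-GR line without dexamethasone, 3 arrays per group, for the tested members of 5 gene lists. Filled points passed an adjusted p of 0.05, open points did not, and lines mark the medians: -1.01 for interferon-stimulated genes, -1.04 for metallothioneins, 0.93 for inflammatory, 0.83 for bone and matrix and 0.02 for proliferation genes.

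Without dexamethasone, 12329 genes differed between the lines, 6167 higher and 6162 lower in the S404A-GR line, with 1421 and 1458 of them at least 2-fold. Adjusted over the list alone, 17 inflammatory genes were higher and 2 lower, and the other 6 called lists gave the counts above. No slide holds vehicle arrays of both lines, and with slide as a block, which links them through the other arrays, 8835 genes were called, 3994 of them higher. The list medians were then -0.99 for interferon-stimulated, -1.29 for metallothionein, 0.85 for inflammatory, 1.00 for matrix, 0.36 for immediate early, -0.53 for heat shock and 0.37 for p53 target genes.

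With dexamethasone, 14732 genes differed between the lines, 7330 higher and 7402 lower in the S404A-GR line, and 10236 with slide as a block. Of the 19 lists, 9 were called with the preset correlation, and 5 of these also with the estimated one. The plan held only counts and shared genes for this comparison. Its list calls were not retested under other scalings or filters, with slide as a block or with arrays left out. Interferon-stimulated genes were lower (21 of 26; median -1.22, adjusted p = 0.0313 with an estimated correlation), and immediate early genes were higher (16 of 23; 0.71, adjusted p = 0.0313 likewise). Inflammatory genes (19 of 24; 1.16), Wnt target genes (16 of 20; 0.74) and p53 target genes (16 of 25; 0.56) were also higher, with adjusted p of 0.0458, 0.0458 and 0.0422 with an estimated correlation. The other 4 lists were called with the preset alone. Metallothioneins were lower (9 of 10; median -1.08, adjusted p = 1.08e-04), but not with an estimated correlation (adjusted p = 0.350). Classical glucocorticoid-induced genes (19 of 33 higher, 7 lower; 0.36, adjusted p = 0.00836), clock genes (10 and 2 of 15; 0.63, 0.0230) and unfolded protein stress genes (12 and 3 of 21; 0.33, 0.0434) were higher, but not with an estimated correlation (adjusted p = 0.164, 0.0779 and 0.528). Median scaling moved the median difference of all genes from 0.03 to 0.14, and 8783 of 15061 called genes were then higher. Across genes, the differences between the lines with and without dexamethasone had a Pearson's r of 0.713.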

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

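The tests of slide and scaling as explanations for the response difference and for the interferon-stimulated genes, and of the background by the level without dexamethasone, were chosen after those results had been seen.

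Of the 97 genes named in the comparisons of both lines' dexamethasone responses, 77 passed the test of the difference between the lines (limma interaction, 3 arrays per group) and 20 did not. Each value is the log2 change in S404A-GR cells minus that in WT-GR cells. Where genes were picked for a large difference, the test is not an independent one.

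FRG2 (-4.35), PTX3 (-4.25), IL3RA (-3.47), ITGB2 (-3.20), ANO1 (-3.17), EDNRA (-2.83), PHACTR3 (-2.09), ARC (-1.55) and NOS2 (-1.37) rose more in WT-GR cells. LPL (-1.20), TG (-1.18), HBZ (-1.13), FTCD (-1.0), CPT1A (-0.96), DLL1 (-0.79) and HBM (-0.74) also rose more there. LAD1 (3.69), KCNH2 (2.84), FABP6 (2.52), HSPA6 (2.40), PDK4 (2.28), FLRT3 (2.21), CDKN1C (1.93), CA2 (1.88) and CARD14 (1.74) rose more in S404A-GR cells. So did PER1 (1.44), FAM90A1 (1.13), NFIL3 (1.04), RGS2 (0.73), KLF15 (0.68) and TAMALIN (0.42).

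INHBE (3.00), IL21R (2.74), ADAMTS6 (2.26), CCN1 (1.75), AMIGO2 (1.57), DNM3 (1.51), GADD45A (1.38), HSPA1A (1.20), SERTAD4 (1.20) and JUNB (1.13) fell more in WT-GR cells. NR1D2 (1.11), JUN (1.10), TGFB2 (1.10), ST6GALNAC5 (1.04), RUNX1T1 (0.76), PLK3 (0.69), DNAJB1 (0.54), PTPRR (0.52) and NR3C1 (0.41) did too. NAV3 (-2.30), CDH1 (-1.20), FGF5 (-1.10), LIF (-0.98) and CNIH3 (-0.97) fell more in S404A-GR cells. RIPOR2 (4.16), TEX14 (3.00), CMKLR2 (2.75), TXNIP (2.55), DDIT4 (1.92), SESN2 (0.83) and FAS (0.78) fell in WT-GR and rose in S404A-GR cells. VCAN (-3.79), LBH (-3.43), ARHGAP25 (-3.38), TRA (-3.31) and EVA1A (-3.08) rose in WT-GR and fell in S404A-GR cells. Some of these genes were near the background in 1 group, so the size of their difference is uncertain. HBZ and CARD14 were well above it on 2 of 3 WT-GR vehicle arrays, NAV3 on 2 of 3 WT-GR dexamethasone arrays and RUNX1T1 on 1 of 3 S404A-GR dexamethasone arrays.

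For CXCL1 (3.66), ACTL8 (2.71), KCTD4 (2.36), KRT5 (-2.30), SPINK13 (2.27), CXCL8 (1.77), BDKRB1 (-1.61), KDF1 (-1.53), GPR65 (-1.42) and KCNJ15 (1.33), no array of at least 1 group was well above background, so the size of the difference is not measured. The lists with a called difference were circadian clock genes (median 0.72), classical glucocorticoid-induced genes (0.38), immediate early genes (0.36) and p53 target genes (0.23), none of them with an estimated correlation.

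The first pattern weighed is the different response itself, called for 7411 genes. If slides were its whole cause, the difference should vanish with slide as a block, but for the 1433 genes with at least a 2-fold difference the blocked value was a median of 1.039 times the unblocked one (quartiles 0.924 and 1.164), with the same sign in 1433. The blocked value compares arrays within slides 1 and 3 only. It rests on 1 WT-GR dexamethasone array, with the lowest quality weight (0.262), and on 1 S404A-GR vehicle array. All arrays of these slides also served to pick the genes, so this is a weak check and no independent test. At least 96% of these 1433 genes were called in the same direction under quantile, median and value table scaling, so they did not depend on the choice among these. The genes were picked for a 2-fold difference, whereas these scalings moved the median of all genes little (in WT-GR cells from 0.06 to between -0.065 and 0.004). Such shifts could hardly undo the calls, so scaling as a cause is not decided by this test. Neither test covered the smaller differences among the 7411 genes. Only 1 of 100 drawn splits of the 12 arrays, the real one, gave as many genes, and the highest other split gave 3. The other splits keep the real difference within their groups, which widens their spread and lowers their counts. The result argues against chance only as far as it lies in the spread between arrays, which is not known to include that between cultures. The receptor form and any other difference between separately made lines stay open and untested, since each receptor form was in 1 line.

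The second pattern is the lower level of interferon-stimulated genes in the S404A-GR line without dexamethasone (median -1.01). The call was lost with an estimated correlation (adjusted p = 0.0689). At the preset correlation the median with slide as a block was -0.991 (adjusted p = 4.38e-04, the highest over the settings, whose lowest was 3.52e-06), which argues against slide as the whole cause. The block links the lines only through the WT-GR dexamethasone arrays, of which slide 1 holds 1. Under quantile, median and value table scaling the median was at or below -0.959, so it did not depend on the choice among these scalings. Scaling as a cause is not decided by this. The receptor form and other differences between the lines stay open and untested.

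The third pattern is that rises of at least 8-fold outnumbered falls, 500 to 60 in WT-GR and 356 to 36 in S404A-GR cells. A candidate explanation is that the background hides deep falls, and 2 filters were used to test it. The filter fixed in advance, on the mean over all arrays, decides nothing, since it admits rises from levels at which a fall would be hidden (80.3% and 90.3% of the 8-fold changes were rises). By the level without dexamethasone, 13593 genes in WT-GR and 13494 in S404A-GR cells had room for an 8-fold change both ways. Among these, rises made up 51.9% in WT-GR cells (40 rises and 37 falls, exact interval 40.3% to 63.5%) against 89.3% among all genes, as the floor would give. In S404A-GR cells they made up 66.7% (40 rises and 20 falls, interval 53.3% to 78.3%) against 90.8%, so the floor and a true excess of rises cannot be told apart there. The intervals treat genes as independent, which they are not, so they may be too narrow, and those of the 2 lines overlap. Genes that are bright without dexamethasone also have more room to fall, so neither share shows how dim genes would behave without a floor. No biological explanation was tested.

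For the comparisons of 3 arrays against 3, the 10 splits are too few for a share under 0.05. Each other split also mixes the groups compared, so the real difference widens its spread and lowers its count. The counts therefore decide nothing about chance. The real split gave 12145 genes in WT-GR cells and 15220 in S404A-GR cells, where the highest other split gave 0, and 12329 between the lines without and 14732 with dexamethasone, where the highest other split gave 1; as many genes came from 1 split, the real one, in each.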

How the results depend on the processing

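The within-slide fits, the alternatives for the shared calls and some of those for the lines with dexamethasone were chosen after the data had been seen. Minimum changes and stricter thresholds lowered counts by construction. At 2-fold the counts were 3653 (WT-GR), 4082 (S404A-GR), 1433 (response difference), 2879 and 3851 (lines without and with dexamethasone) and 2319 (shared calls). At 1.5-fold they were 6621, 8627, 3869, 6185, 8475 and 4576, and at an adjusted p under 0.01 the response difference was called for 4301 genes. Under the other alternatives every count of genes stayed within 1.5 times its value; leaving out 1 array gave 10886 to 12904 genes in WT-GR cells and 6131 to 7553 for the response difference.

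Called lists depended on the test. With an estimated correlation 0 lists were called in the WT-GR, S404A-GR, response and vehicle comparisons, and with fry, which does not compare a list with other genes, 17, 18, 13 and 12 of 19. In WT-GR cells 3 lists were called, but 1 with the filter on all 12 arrays, 1 with slide as a block and 1 to 4 with 1 array left out. For the response difference 4 were called, and 7 without a filter on dim probes. The cause was not tested.

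Directions without a camera or limma call were reversed for CLOCK in the response difference without WT-GR vehicle array 2 (-0.40; up to 2.14 with another array left out) and for epithelial markers in WT-GR cells under quantile scaling (-0.17), the value table (-0.14) and the all-array filter (-0.039). Medians of uncalled lists also changed sign for metabolic genes in S404A-GR cells with slide as a block (-0.013), for metabolic genes in WT-GR cells without WT-GR dexamethasone array 1 (0.038) for inflammatory genes in WT-GR cells with normexp correction (0.067), and for epithelial markers in WT-GR cells under median scaling (-0.101) and without WT-GR vehicle array 2 (-0.006) or dexamethasone array 2 (-0.064). For metabolic genes in WT-GR cells fry gave a rise at a median of -0.076. Replicate numbers were not treated as pairs. Residuals of arrays with the same number correlated across genes at r of -0.372 to 0.202. Arrays with different numbers were not compared, so whether the numbers mark pairs is not settled. With the number as a block 11701, 14832, 6750, 11900 and 14447 genes were called, and 8720 shared. Signal over background limits the dim genes, since 69.1% to 77.9% of probes were well above it per array.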

Other observations

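The metabolic and epithelial lists were picked for description, and the chromosome windows named, after the results had been seen, whereas the test of neighbouring genes was written before.

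Of 31 glucose and lipid metabolism genes, 11 rose and 11 fell in WT-GR cells, and 13 rose and 9 fell in S404A-GR cells, with the same counts adjusted over the list alone. LPL, the lipoprotein lipase gene, rose 27.8-fold in WT-GR and 12.1-fold in S404A-GR cells, and CPT1A, which brings fatty acids into mitochondria, 14.1-fold (3.81 ± 0.11) and 7.21-fold (2.85 ± 0.11). PDK4 rose by 4.56 and 6.84. The glucose-6-phosphatase gene G6PC1, not well above background without dexamethasone, rose at least 2.98-fold in WT-GR cells. In S404A-GR cells, with 2 of 3 dexamethasone arrays well above background, it rose at least 1.76-fold (adjusted p = 0.00213) and lost its call with slide as a block (range over 18 alternatives 9.95e-04 to 0.0681). With normexp correction G6PC1 rose by 1.19 and 0.91 in the lines, and CPT1A by 2.50 in WT-GR cells. The list was not called in WT-GR cells (adjusted p = 0.740; test down with a median of -0.08 and a mean of 0.33) or S404A-GR cells (median 0.11, adjusted p = 0.877).

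Of 15 epithelial and keratinocyte markers, 5 rose and 2 fell in WT-GR cells, and 8 rose and 3 fell in S404A-GR cells (6 and 2, and 9 and 3, adjusted over the list alone). The keratin gene KRT5 rose at least 29.5-fold in WT-GR cells, and the transcription factor gene GRHL2 at least 4.75- and 3.51-fold in the lines. In S404A-GR cells KRT5 rose too (4.53 ± 0.55, and 5.87 with slide as a block or within slide 3), but 1 of 3 vehicle arrays was well above background, so the size is not measured well. The E-cadherin gene CDH1 changed by -1.44 ± 0.08 and -2.63 ± 0.08, and SFN by -1.19 ± 0.12 and -1.10 ± 0.12. With normexp correction the changes in WT-GR and S404A-GR cells were 3.48 and 2.24 for KRT5, 1.53 and 1.14 for GRHL2, and -0.87 and -1.17 for CDH1. The list was not called in either line (median 0.03, adjusted p = 0.785, and median 0.36, adjusted p = 0.710).

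In WT-GR cells the other lists were not called. The counts of rises and falls were 5 and 0 of 10 metallothioneins, 4 and 6 of 15 clock genes, 5 and 12 of 31 apoptosis regulators, 8 and 10 of 32 proliferation genes, 5 and 7 of 20 Wnt target genes, 10 and 5 of 26 interferon-stimulated genes and 10 and 3 of 19 ion transport genes. They were 4 and 9 of 25 p53 target genes, 4 and 9 of 21 unfolded protein stress genes, 6 and 10 of 33 receptor and GSK-3 partner genes (median -0.09, mean 0.06, test down) and 14 and 11 of 31 matrix genes (median 0.13, mean 0.16, test down). Leukocyte markers gave 4 and 2 of 16, and adipocyte, neuronal and muscle markers 3 and 2 of 15.

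Under the hypothesis that chromosome segments were gained or lost in 1 line, neighbouring genes should differ together. Without dexamethasone, the medians of 452 windows of 50 neighbouring genes had an SD of 0.207, which was 2.587 times the mean of 1000 shuffles (highest shuffle 0.0895). Such segments may therefore contribute, but neighbours also moved together with dexamethasone (ratio 1.747 in WT-GR and 1.604 in S404A-GR cells), a change measured within 1 line, so grouping alone does not show them. The windows drew on 23042 genes or unnamed features with a position, and of all 23343 tested, 14971 had a current symbol. Several features may belong to 1 gene, and the shuffles part them, so some of each ratio could come from this. Window medians between the lines without and with dexamethasone correlated across windows (r = 0.836). On chromosome 20, from 56.9 to 61.1 Mb, 44 of 50 genes or unnamed features were higher in the S404A-GR line (median 0.644, and 0.682 with dexamethasone). On chromosome 21, from 29.4 to 34.2 Mb, 44 of 50 were lower (-0.653). No copy number was measured.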
